A study of Arabidopsis thaliana with 9 samples.

How the data were processed

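RNA abundance was measured on Affymetrix ATH1 GeneChips in seedlings of Arabidopsis thaliana. The 9 arrays fall into 3 genotypes with 3 arrays each: a jmj24 mutant from a stock centre, a line that overexpresses JMJ24 from the 35S promoter (35S::JMJ24), and wild type. The extraction protocol gives seedlings aged 9 days, while the growth protocol of the labels gives 10-14 d before analysis. The labels do not resolve this, and 9 days is stated here from the extraction protocol. Each array was assigned to its genotype from its sample title, which also gives a replicate number.

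The deposited values were produced by the authors with the affy package, per the submitters' processing notes. The version of affy, and the methods of background correction, normalization and summary, are not given in the sources used here. The deposited table holds 1 value for each of 22810 probe sets and each array. No source names the scale. The values lie between 2.634 and 14.7 on all arrays and the medians of the arrays lie between 7.824 and 7.873, as log2 summaries of normalized scanner signals would. The deposited values were therefore read as log2 values, and every fold change below rests on that reading. They were used without further transformation.

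Of the 22810 probe sets, 64 are array controls and the other 22746 were tested. Names came from the platform annotation, updated through the RefSeq gene table of assembly TAIR10.1, which was used only for names, gene types and the order of genes along chromosomes. No coordinates are given, because the sources used here name no genome build for the array. In that annotation 13513 tested probe sets name 1 gene, 503 name several and 8730 are unnamed. Of the 13513, 13484 could be matched to a locus. They cover 13333 loci, of which 145 are measured by several probe sets. A locus with several probe sets was represented by the probe set with the highest mean over the 9 arrays. An unnamed probe set is reported by its ID, which does not mean that it measures no known gene. No probe set is paired with JMJ24 (AT1G09060) in the annotation used here, so the targeted gene could not be checked.

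Differences were tested with limma 3.58.1 in R 4.3.3. A linear model with 1 mean per genotype was fitted to all 9 arrays, so that the genotypes share 1 estimate of the spread with 6 residual degrees of freedom. Variances were moderated by empirical Bayes, with 3.335 prior degrees of freedom. The tests are two-sided, and p-values were adjusted by the Benjamini-Hochberg method within each comparison. A probe set passed the test at an adjusted p under 0.05 with no minimum fold change. The comparisons were the mutant against wild type, 35S::JMJ24 against wild type, and the mutant against 35S::JMJ24, with a moderated F test over the 3 genotypes. The standard error of a log2 difference had a median of 0.0923. The number of arrays limits the precision. The labels do not say that the replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

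The design, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. For each comparison with wild type, the rule names JMJ24, QQS, and the 10 largest rises and 10 largest falls among loci past the threshold whose values do not overlap between the groups. It also names up to 4 members of each list by smallest p, and loci past the threshold in opposite directions in both lines. For the mutant against 35S::JMJ24 it names the 5 largest rises and 5 largest falls. Where fewer than 5 loci pass, it adds the 10 with the smallest p. Items outside the rule are said to have been chosen after their values were seen.

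The gene lists comprised 16 written by locus, with 346 loci in all, of which 51 are measured under a name here. They cover silencing-sensitive loci, DNA methylation machinery, other jumonji proteins, flowering time, the circadian clock, heat shock, salicylic acid defence, jasmonate and ethylene defence, cold and abscisic acid response, flavonoid synthesis, starch metabolism, phosphate starvation, cell division, photosynthesis, root cells, and seed storage. A further 4 were defined by annotation: transposable element genes, plastid-encoded genes, mitochondria-encoded genes, and the genes beside JMJ24. The annotation used here has no type for transposable elements, so loci typed as pseudogene (923) or transcribed pseudogene (66) replaced the first of these. That replacement was chosen after the annotation was seen. The type does not separate transposon fragments from copies of other genes. No member of the phosphate, seed storage and mitochondrial lists is measured under a name here. The 12 lists with at least 3 measured members were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. The p-values were adjusted over the lists of a comparison. Members were also adjusted over the list alone.

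The replicate numbers were checked for pairing before any blocked fit was compared. Between the mutant and 35S::JMJ24 the residuals of arrays with the same number correlated at 0.43, 0.17 and 0.17 across probe sets, so the numbers pair the arrays in that comparison, as a feature of the data that no label explains. In the comparisons with wild type the correlations of numbers 1, 2 and 3 were 0.44, 0.06 and 0.3 for the mutant. For 35S::JMJ24 they were 0.42, 0.01 and 0.21. Those of numbers 1 and 3 were near or above the values between the lines. Only that of number 2 was lower. On the ground of number 2 alone the numbers were not taken to pair arrays there, and numbers 1 and 3 go against that choice. Whether the numbers also pair the wild-type arrays is therefore left open. No block was in the model, so its counts leave any pairing out. With the replicate number as a block, 607 probe sets differed between the mutant and wild type, among them all 259 that the model called.

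Both comparisons with wild type use the same 3 wild-type arrays. Their agreement was therefore set against 100 simulated data sets with unchanged groups, independent arrays and independent probe sets. The simulation was repeated, after its result was seen, with the noise of arrays of the same number correlated as their residuals are. With 3 wild-type arrays, no split could leave 2 on each side. RNA quality was measured as the 3-prime minus 5-prime log2 signal of the GAPDH, actin and ubiquitin controls. It was compared by two-sided exact permutation tests, which with 3 arrays against 3 cannot go below p = 0.1. The highest mean of 27 bacterial control probe sets served as a mark of background; below it the size of a change is uncertain. The model was tested on simulated data for the mutant and wild type with 22746 probe sets. It recovered 60.3% of changes of 0.5 on the log2 scale, 99.4% of changes of 1 and 100% of changes of 2, with 6.08% false calls. A list shifted on purpose was called in 5 of 5 runs, and 0 other lists were. The simulated probe sets were independent, so these runs cannot show how often camera falsely calls a list of correlated genes. In the data the estimated correlation was 0.627 for plastid-encoded genes and 0.204 for annotated pseudogenes.

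Alternatives covered a replicate block, renewed quantile normalization, equal array medians, removal of dim probe sets, only probe sets without a cross-matching suffix, other variance models, array weights, 2 groups at a time, stricter thresholds, and each array left out in turn. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3.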

Results

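Transcript levels were compared among 3 genotypes of Arabidopsis thaliana seedlings, aged 9 days by the extraction protocol, with 3 ATH1 arrays for each genotype. JMJ24 belongs to the jumonji family, whose best known members are histone demethylases. The jmj24 mutant carries a disruption of this gene, and the 35S::JMJ24 line transcribes it from a strong viral promoter. The study asked what JMJ24 does in the silencing of transposons. Across probe sets, the correlation between any 2 arrays lay between 0.9918 and 0.9976. JMJ24 itself was not matched to a probe set in the annotation used here, so its level in the arrays is not reported under its name. On the component that holds 40.1% of the variation within genotypes, the array numbered 1 scored lowest in each genotype. The scores were -9.74 for mutant 1, -12.3 for 35S::JMJ24 1 and -25.3 for wild type 1, the lowest of all arrays. The mean scores were 5.44 in the mutant, 0.88 in 35S::JMJ24 and -6.32 in wild type. The 3-prime minus 5-prime signal of the control transcripts was 3.97 ± 0.043 in the mutant, 3.96 ± 0.072 in 35S::JMJ24 and 4.0 ± 0.035 in wild type (log2, mean ± SD, n = 3). In this measure of RNA quality the mutant differed from wild type by -0.0265 and 35S::JMJ24 by -0.0423 (two-sided exact permutation tests, p = 0.5 and 0.4). With 3 arrays against 3 these exact tests cannot go below p = 0.1, and the shift of 35S::JMJ24 exceeds the SD of the wild-type arrays.

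The comparison of the mutant with wild type asks which transcripts depend on an intact JMJ24 gene. Falls outnumbered rises. AT4G04750 fell from 7.12 ± 0.242 in wild type to 4.69 ± 0.349 in the mutant (log2 level, mean ± SD, n = 3), a log2 change of -2.43 (SE 0.192, adjusted p = 0.000557). Its mutant level lies below the brightest of 27 bacterial controls (5.8), taken as a mark of background, so the size of this fall is uncertain. MAP1B (AT3G25740), a methionine aminopeptidase, the kind of enzyme that removes the initial methionine from new proteins, fell from 10.9 ± 0.058 to 8.71 ± 0.158, a log2 change of -2.18 (SE 0.084, adjusted p = 1.15e-05). QQS (AT3G30720), an Arabidopsis gene that affects starch content and whose activity is known to depend on DNA methylation, fell from 8.54 ± 0.161 to 7.60 ± 0.307, a log2 change of -0.94 (SE 0.181, adjusted p = 0.0471). AT5G19890 rose from 6.46 ± 0.175 to 7.67 ± 0.213, a log2 change of 1.21 (SE 0.131, adjusted p = 0.00309).

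Of 22746 probe sets, 259 differed between the mutant and wild type, 70 higher and 189 lower in the mutant. At an unadjusted p under 0.05 there were 2667, where chance alone gives 1137. The 259 comprise 146 that name 1 gene, 6 that name several and 107 that are unnamed here. The 146 loci comprise 36 that rose and 110 that fell. A change of at least 2-fold was seen for 52 probe sets, 6 higher and 46 lower. In all 259 the 3 mutant values lay on one side of the 3 wild-type values. Such a separation held for 16% of all probe sets, against 10% by chance. The count was 124 without wild type 2, 158 without wild type 1, 159 without wild type 3, 145 without mutant 2 and 139 without mutant 3. Without the 3 arrays numbered 1 it was 53, of which 48 were among the 259. It was 607 with the replicate number as a block, 241 of them higher, and 641 with array weights, 229 of them higher.

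The other large falls in the mutant were in AT3G60180 (log2 change -1.83), AT2G40570 (-1.66), AT2G46910 (-1.50), AT1G08310 (-1.44) and AT5G40180 (-1.29), with adjusted p from 0.000155 to 0.0146. The mutant level of AT2G40570 (5.79) lies at the mark of background. AT2G15042 also passed as lower (adjusted p = 0.000496), but at 5.75 in wild type and 4.27 in the mutant it lies below the mark in both, and no size is given. ATIM (AT5G52910), the plant relative of the animal Timeless gene, fell by 1.44 on the log2 scale (adjusted p = 0.00601). The pseudogene AT1G43590 fell from 9.62 ± 0.030 to 8.14 ± 0.064, a log2 change of -1.48 (SE 0.078, adjusted p = 7.84e-05). Among rises, AT3G53310 (1.1), AT1G78450 (1.04) and AT5G01940 (0.79) followed AT5G19890, with adjusted p from 0.00251 to 0.0349. AT1G26530, AT3G60650 and AT2G15630 also passed as higher (adjusted p = 0.00429, 0.0342 and 0.0428), at 4.72, 4.72 and 4.81 in wild type and 5.70, 5.60 and 5.57 in the mutant, all below the mark of background. SDS (AT1G14750), which encodes a cyclin of meiosis, rose by 0.76 (adjusted p = 0.0486), and the pseudogenes AT3G21020 and AT1G27285 rose by 0.74 each (adjusted p = 0.00397 and 0.0179). These 3 lay below the mark in wild type (5.21, 5.74 and 5.35), so the size of their rise is uncertain.

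For 26 calls in the mutant each array was left out in turn: the 20 largest changes of named genes, QQS, AT2G11140 and 4 unnamed probe sets. Of these, 17 were kept whichever array was left out and 9 were lost without some array. QQS lost its call without any array except mutant 3 and 35S::JMJ24 3, with a log2 change between -1.09 and -0.79 and an adjusted p of up to 0.148, and also after renewed quantile normalization (-0.93, adjusted p = 0.0514). AT1G78450 lost it without any array except mutant 1, 35S::JMJ24 1 and 35S::JMJ24 3 (adjusted p up to 0.117), AT3G60650 without any except mutant 2 and 35S::JMJ24 1 (up to 0.133), and AT5G01940 without any except mutant 2 and 35S::JMJ24 2 (up to 0.146). SDS lost it without any array except 35S::JMJ24 1 (up to 0.186), and AT2G15630 without any except wild type 3 (up to 0.168). AT1G27285 lost it without mutant 2, wild type 1 or wild type 2 (up to 0.0701), AT1G08310 without wild type 2 or 3 (up to 0.072), and the pseudogene AT2G11140, described below, without wild type 2 (0.0582).

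**Figure D1:**
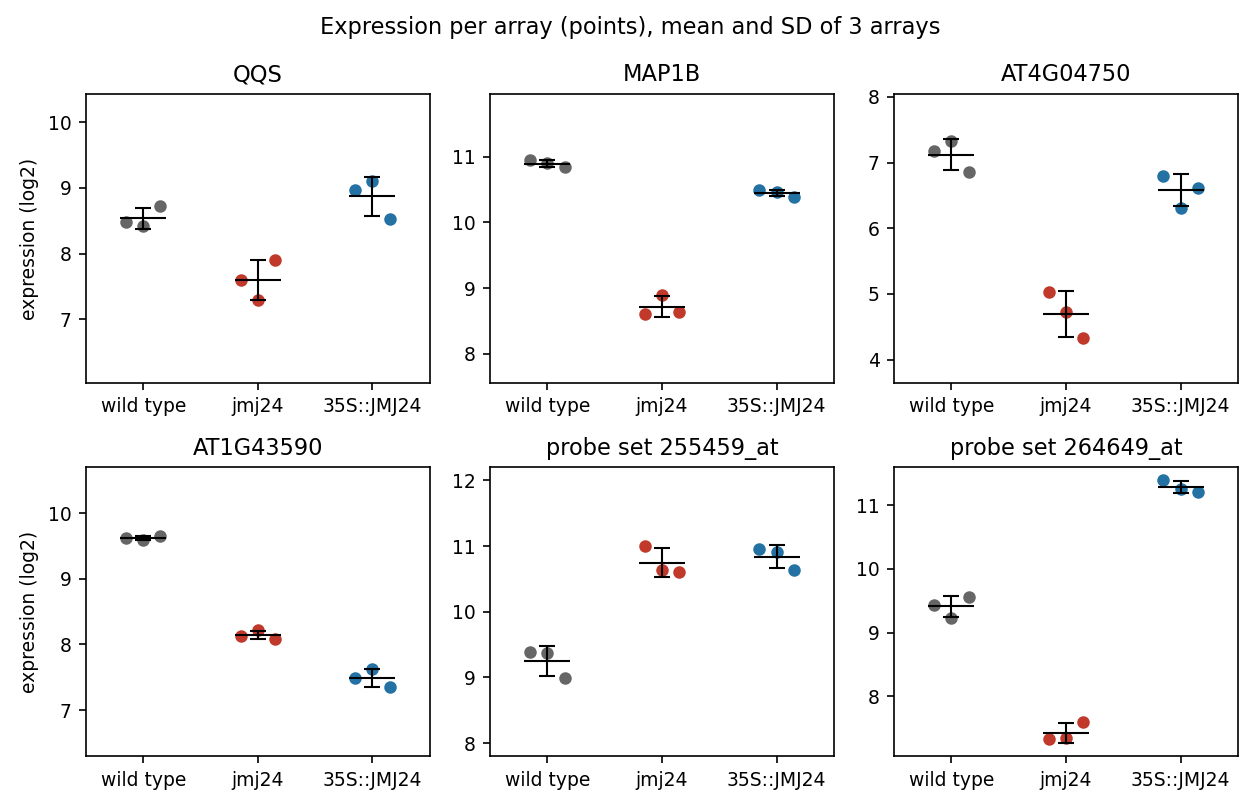
Log2 expression of QQS, MAP1B, AT4G04750, AT1G43590 and the unnamed probe sets 255459_at and 264649_at in each array of wild type, jmj24 mutant and 35S::JMJ24. Points are arrays, the horizontal bar is the mean and the error bar the SD of 3 arrays; the mutant lies below wild type in all panels but that of 255459_at, and 264649_at falls from 9.41 in wild type to 7.43 in the mutant and reaches 11.3 in 35S::JMJ24.

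Among the silencing-sensitive loci, 5 of 18 were measured under a name. QQS fell in the mutant, 0 rose and 4 did not pass. Adjusted over the list alone the count was also 1. The 4 others are annotated pseudogenes: AT4G03650 changed by 0.21, AT4G03870 by -0.08, AT4G16870 by 0.10 and AT2G01840 by 0.03 on the log2 scale. AT4G03650, AT4G03870 and AT2G01840 lay below the mark of background, at 3.53, 3.78 and 4.49 in wild type, and AT4G16870 turned to -0.01 without mutant 3. The median of the list was 0.0284 and its mean -0.137, and camera placed it lower without a call (adjusted p = 0.732). The list kept no member past the threshold, by limma, without any 1 of mutant 1, mutant 2, 35S::JMJ24 1, 35S::JMJ24 2 or the wild-type arrays, nor after renewed quantile normalization, where the count was 0.

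The 989 annotated pseudogenes stood for transposon-derived loci. In the mutant 2 rose (AT3G21020 and AT1G27285) and 2 fell (AT1G43590 and AT2G11140, the latter by 0.63 on the log2 scale, adjusted p = 0.0108). The other 985 did not pass, and 42 had an unadjusted p under 0.05. Adjusted over the list alone 4 passed. The list as a whole lay slightly higher, with a median log2 change of 0.0471, a mean of 0.0448 and 687 members above wild type (camera, adjusted p = 0.0301). The call was lost with an estimated correlation (adjusted p = 0.823 with an estimated correlation). It was also lost without mutant 2 (mean 0.00735, adjusted p = 0.637), without wild type 2 (0.0429, 0.0635) and without wild type 1, where the mean turned to -0.00102 (0.844). Without mutant 1 the mean was 0.0785 and without wild type 3 it was 0.0925. Most members were dim, with a median level of 4.17, and 18% lay above the brightest of 27 bacterial controls (5.8), against 73.5% of 12344 other loci. With the dimmer 50% of probe sets left out the mean was -0.0225, and after renewed quantile normalization it was 0.0226 with no call.

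Plastid-encoded genes, which serve photosynthesis and plastid translation, lay lower in the mutant as a group. Of 69 measured, 0 passed singly by limma (1 at an unadjusted p under 0.05, 0 adjusted over the list alone), while 65 had a lower mean. The median log2 change was -0.0908 (camera, adjusted p = 8.16e-06). The call was lost with an estimated correlation (adjusted p = 0.823 with an estimated correlation). The smallest p belonged to psaJ (-0.30), ndhG (-0.18), psaI (-0.18) and ycf4 (-0.19), with adjusted p from 0.362 to 0.458. Wild-type arrays differed among themselves, with list medians of -0.07, 0.19 and 0.12 against each gene's mean over 9 arrays. The mean change of the list was -0.101; it was -0.0618 without mutant 2 (adjusted p = 0.0545), -0.0493 without wild type 2 (0.121) and -0.18 without wild type 1.

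No member of the remaining fixed lists passed in the mutant by limma. The counts at an unadjusted p under 0.05 were 1 for flowering time (SMZ, 0.17), 1 for cold and abscisic acid response (COR15B, 0.21), 1 for root cells (EXPA18, 0.47, and 0.23 without wild type 1) and 0 for all others. Of the DNA methylation machinery, 1 of 44 genes was measured under a name: DME, a DNA glycosylase that removes methylated cytosine, changed by -0.11. Its other 2 probe sets read -0.12 and 0.12. Of 20 other jumonji genes 11 were measured, with a median of 0.00806. The flowering regulator FD, below the mark of background, read -0.01, the clock gene GI by -0.01, SAG101 of salicylic acid defence by 0.09 and PRL of cell division by -0.05. Medians were 0.0665 for 5 heat shock genes, 0.114 for 3 genes of jasmonate and ethylene defence, -0.11 for 5 of cold and abscisic acid response, and -0.0553 for 5 of flavonoid synthesis. They were -0.0146 for 4 of starch metabolism, -0.0658 for 4 of photosynthesis in green tissue, and 0.304 for 3 of root cells. The 5 measured genes beside JMJ24 had a median of -0.0366, a mean of 0.0189 and a lower camera direction, and the highest was SRC2 (0.27). None of these lists was called by camera (adjusted p from 0.641 to 0.97).

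The comparison of 35S::JMJ24 with wild type asks what excess JMJ24 transcript changes. Of 22746 probe sets, 4 differed, 2 higher and 2 lower, with 1690 at an unadjusted p under 0.05 where chance gives 1137. AT1G43590, annotated as a pseudogene, was the 1 named locus among them. It fell from 9.62 ± 0.030 to 7.48 ± 0.138 (log2 level, mean ± SD, n = 3), a log2 change of -2.14 (SE 0.078, adjusted p = 6.94e-06). The 3 others are unnamed and were chosen after their values were seen. Probe set 264649_at rose from 9.41 ± 0.163 to 11.3 ± 0.098, a log2 change of 1.87 (SE 0.106, adjusted p = 0.000204), 255459_at rose by 1.59 (SE 0.145, adjusted p = 0.00919) and 261927_at fell by 0.55 (SE 0.062, adjusted p = 0.0434). QQS changed by 0.33 and did not pass (SE 0.181, adjusted p = 0.695).

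All 4 had no overlap with wild type, which held for 11.7% of all probe sets against 10% by chance. The calls of AT1G43590 and 264649_at were kept whichever array was left out. That of 255459_at was lost without 35S::JMJ24 1, 35S::JMJ24 2 or wild type 2 (adjusted p up to 0.116), which left 2 calls each time, and that of 261927_at was lost without any 1 of the 9 arrays (up to 0.279). Without the 3 arrays numbered 1, the count was 1. The next smallest p belonged to loci that did not pass: AT3G21020 (0.69, adjusted p = 0.0573) and AT2G15042 (lower, 0.0573, below the mark of background in both groups), which had changed the same way in the mutant, and AT4G24450, a relative of the starch-phosphorylating dikinases (0.61, 0.0914). After them came AT5G19500 (-0.40), the defensin gene LCR67 (0.92, from below the mark), AT5G06190 (-0.47), AT1G60610 (0.41), AT4G29030 (0.49) and AT1G61590 (0.42), with adjusted p from 0.171 to 0.264.

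In the 35S::JMJ24 line all 69 plastid-encoded genes had a lower mean than in wild type, with a median log2 change of -0.127 (camera, adjusted p = 1.22e-18). The call was lost with an estimated correlation (adjusted p = 0.958 with an estimated correlation). Singly 0 passed by limma, 8 at an unadjusted p under 0.05 and 0 adjusted over the list alone. The smallest p belonged to psbK (-0.25), psaJ (-0.33), ndhG (-0.22) and ndhK (-0.24). The mean change was -0.143; it was -0.222 without wild type 1 and -0.0914 without wild type 2. The annotated pseudogenes were not called as a list, with a median of 0.0546, a mean of 0.0428 and 680 of 989 higher (camera, adjusted p = 0.182). They were called without 35S::JMJ24 3 (mean 0.059, adjusted p = 0.0354) and without wild type 3 (0.0905, 0.00013), at the preset correlation. With an estimated correlation, not run in those settings, the whole list had an adjusted p of 0.958. The mean turned to -0.003 without wild type 1 and fell to 0.00799 without 35S::JMJ24 2. The mean was -0.0164 for members above the brightest bacterial control. AT1G43590 fell, 0 rose and 988 did not pass, with 70 at an unadjusted p under 0.05 and 2 adjusted over the list alone, AT1G43590 and AT3G21020.

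**Figure D2:**
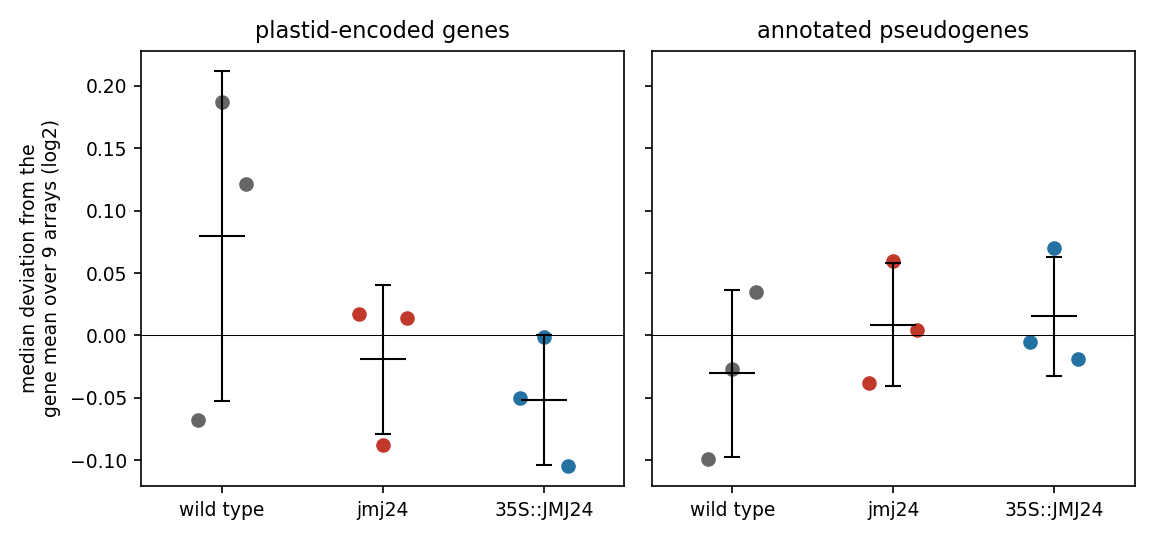
Median deviation of plastid-encoded genes (left) and annotated pseudogenes (right) from each gene's mean over 9 arrays, in log2 units, for each array (points) of wild type, jmj24 mutant and 35S::JMJ24, with the mean and SD of 3 arrays. The plastid medians of the wild-type arrays run from -0.07 to 0.19, wider than the differences between genotypes.

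No other list had a member past the threshold in 35S::JMJ24 by limma. The root cell list came nearest: the root hair expansins EXPA7 (0.40) and EXPA18 (0.47) both had an unadjusted p under 0.05, and 2 of 3 passed when adjusted over the list alone, while the camera call was missing (adjusted p = 0.423). The same genes read 0.30 and 0.47 in the mutant. Much of this rests on wild type 1: without it EXPA7 and EXPA18 read 0.22 and 0.23 in 35S::JMJ24, and 0.13 and 0.23 in the mutant. Counts at an unadjusted p under 0.05 were 0 for the others. The silencing-sensitive loci had a median of 0.0014 (AT4G03650 0.16, AT4G16870 -0.18, AT2G01840 -0.08; adjusted p = 0.941). DME changed by -0.08, SMZ by 0.09, FD by 0.12, GI by 0.01, SAG101 by 0.20 and PRL by -0.04. Medians were 0.00147 for other jumonji genes, 0.0768 for heat shock, -0.289 for jasmonate and ethylene defence, 0.0375 for cold and abscisic acid response, and 0.0741 for flavonoid synthesis. They were -0.0329 for starch metabolism, -0.0441 for photosynthesis and 0.000593 for the genes beside JMJ24. The median differed in sign from the mean for jumonji genes (mean -0.0108) and cold response (-7.89e-05), and from the camera direction for jumonji genes and the genes beside JMJ24. Adjusted p over these lists ran from 0.474 to 0.941.

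A gene under the control of JMJ24 dose would move in opposite directions in the mutant and in 35S::JMJ24, and the comparisons with wild type were set side by side to look for such genes. All 4 probe sets that differed in 35S::JMJ24 also differed in the mutant. Probe set 264649_at alone went opposite ways, lower in the mutant (-1.99, adjusted p = 7.84e-05) and higher in 35S::JMJ24 (1.87). AT1G43590 and 261927_at (mutant -0.56, adjusted p = 0.0034) fell in both, and 255459_at (mutant 1.50, adjusted p = 0.00171) rose in both. Independent lists of these sizes would share 0.00615 rises and 0.0166 falls. These lists are not independent, because both use the same wild-type arrays, so such values are too low a mark for the overlap. With unchanged groups and the same wild-type arrays, 0 of 100 simulated data sets had a probe set called in both. With the mutant and 35S::JMJ24 arrays paired by replicate number it was 1 of 100. Where no group changes, the adjustment leaves few calls in any comparison, so these counts were bound to be low. They do not weigh against noise in the shared wild-type arrays. No named locus was past the threshold in opposite directions.

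Across all probe sets, which are not independent replicates, the log2 changes of the lines correlated at r = 0.659, where simulated unchanged groups gave 0.501 on average and 0.52 at most. That simulation took the arrays as independent. Like those below, it also drew the probe sets independently, so its highest values understate what correlated probe sets could give. With the mutant and 35S::JMJ24 arrays correlated by replicate number as their residuals are, it gave 0.629 on average and 0.64 at most, while with the arrays of all 3 genotypes correlated by number it gave 0.511 and 0.528. How much of the excess in r comes from pairing therefore depends on whether the wild-type arrays share it. The labels do not say, and the residuals are mixed. Wild-type arrays 1, 2 and 3 correlated with the mutant arrays of their number at 0.44, 0.06 and 0.3, and with those of 35S::JMJ24 at 0.42, 0.01 and 0.21. The setting that gave 0.629 leaves these correlations out, and the one that gave 0.511 uses them all as measured. Numbers 1 and 3 go against leaving them out, while number 2 does not. The covariance of these log2 changes was 0.0173, of which the shared wild-type arrays account for 0.00635 in the simulation, a difference of 0.011. Shared arrays and pairing together gave 0.00797 in the first case and 0.00492 in the second. The signs matched in 73.6% of probe sets, against 66.7% in the simulation, and 71.6% and 67% with the pairing. Part of the remaining excess may come from the shared wild-type arrays, which were too few to split. Of the 259 probe sets changed in the mutant, 245 had the same sign in 35S::JMJ24, and the median ratio of the change in 35S::JMJ24 to that in the mutant was 0.379. With effects in the mutant alone, the simulated ratio was 0.0176 on average and 0.045 at most, or 0.0547 at most with the pairing. That simulation took the measured changes of the 259 as true effects. They already hold the error of the wild-type arrays, so the simulated ratio is too low, by an amount not tested.

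**Figure D3:**
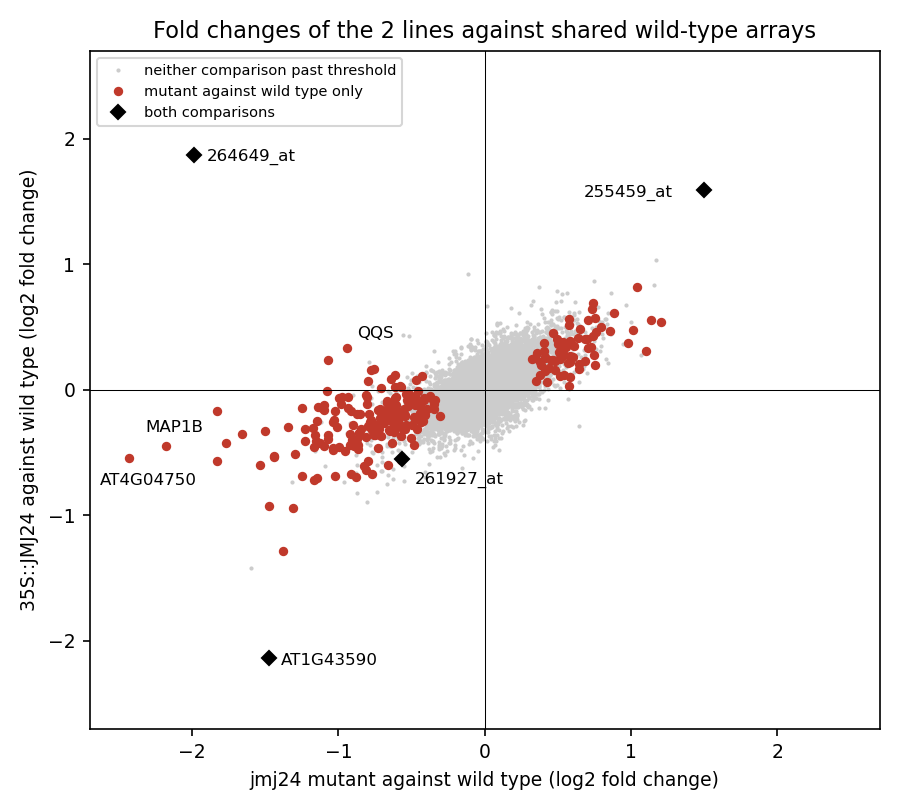
Log2 fold change against wild type of each probe set in the jmj24 mutant (horizontal) and in 35S::JMJ24 (vertical). Grey points passed in neither comparison, red points in the mutant only, and black diamonds in both; of the diamonds, 264649_at lies in the upper left, while AT1G43590 and 261927_at lie at the lower left and 255459_at at the upper right.

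The direct comparison of the mutant with 35S::JMJ24 asks what separates loss from excess of JMJ24 and uses no wild-type array for its difference. Most differences were lower levels in the mutant. AT4G04750 was lower by a log2 change of -1.89 (SE 0.192, adjusted p = 0.00598), MAP1B by -1.73 (SE 0.084, adjusted p = 4.78e-05), AT3G60180 by -1.66 (SE 0.116, adjusted p = 0.000876) and AT2G40570 by -1.31 (SE 0.103, adjusted p = 0.0012); the mutant levels of AT4G04750 and AT2G40570 lie below the mark of background, which leaves the size uncertain. QQS stood at 7.60 ± 0.307 in the mutant and 8.87 ± 0.301 in 35S::JMJ24, a log2 change of -1.27 (SE 0.181, adjusted p = 0.0283). Higher in the mutant were AT3G53310 (0.79, adjusted p = 0.0283), AT1G43590 (0.66, adjusted p = 0.0138) and AT3G25790 (0.52, adjusted p = 0.0389).

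In all 56 probe sets differed, 6 higher and 50 lower in the mutant, with 1440 at an unadjusted p under 0.05 where chance gives 1137. They cover 34 named loci, 3 higher and 31 lower, and 13 changed at least 2-fold. Of the 56, 53 also differed between the mutant and wild type, 52 of them in the same direction. Outside the rule for named genes, the unnamed probe sets with the smallest p were chosen after their values were seen. They were 264649_at (-3.86, adjusted p = 5.21e-07) and 249729_at (-1.30, adjusted p = 0.00117, with the mutant level below the mark of background). Probe sets 255459_at and 261927_at did not differ between the lines (-0.09 and -0.01, adjusted p = 0.966 and 0.991). The moderated F test over the 3 genotypes called 161 probe sets, with 2152 at an unadjusted p under 0.05. Its count ran from 68 to 137 with an array left out and was 292 with the replicate number as a block.

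The count of 56 became 14 without 35S::JMJ24 1, 15 without 35S::JMJ24 2, 29 without 35S::JMJ24 3, 26 without mutant 2, 25 without mutant 3, 34 without wild type 2 and 2 without the 3 arrays numbered 1. QQS lost its call without any array except mutant 3, 35S::JMJ24 3 and wild type 3 (adjusted p up to 0.152), AT3G53310 without any except mutant 2 and 35S::JMJ24 3 (up to 0.152), AT3G25790 without any except mutant 3 (up to 0.179), and AT1G43590 without mutant 2 or 35S::JMJ24 1 (up to 0.0829).

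Among the lists in this comparison, QQS was the 1 silencing-sensitive locus that fell, also adjusted over the list alone, and the list had a median of 0.0521, a mean of -0.184 and no camera call (adjusted p = 0.903). QQS is the only member of the fixed lists, annotated pseudogenes apart, past the threshold here. Of the pseudogenes, AT1G43590 was higher in the mutant and 988 did not pass, with a median of -0.0091, a mean of 0.00198 and a camera direction towards higher (adjusted p = 0.599; adjusted p = 0.933 with an estimated correlation). At the preset correlation the list was called as higher among members above the brightest bacterial control (mean 0.0656, adjusted p = 0.000549) and without the dimmest 30% or 50% of probe sets (0.0718 and 0.1). An estimated correlation was not run in those settings. AT2G11140 read -0.52 (adjusted p = 0.0629) and passed with the replicate number as a block (adjusted p = 0.034). Leaving out 35S::JMJ24 2 led to a call of the pseudogene list (mean 0.0368, adjusted p = 0.0201), and leaving out mutant 2 (-0.0354), 35S::JMJ24 1 (-0.0166) or 35S::JMJ24 3 (-0.0142) turned its mean. Plastid-encoded genes were higher in the mutant than in 35S::JMJ24 as a list, with 56 of 69 higher, a median of 0.035 and 0 called singly by limma or at an unadjusted p under 0.05 (camera, adjusted p = 0.00203; adjusted p = 0.933 with an estimated correlation). Their mean of 0.0421 became 0.0216 without mutant 1 (adjusted p = 0.262), 0.0238 without mutant 3 (0.143), 0.0132 without 35S::JMJ24 3 (0.156), 0.0809 without mutant 2 and 0.0706 without 35S::JMJ24 2. The remaining lists had 0 members past the threshold by limma, 0 at an unadjusted p under 0.05, and camera adjusted p from 0.449 to 0.903; median and mean differed in sign for other jumonji genes (-0.00198 and 0.0193) and starch metabolism (0.0146 and -0.00131), and the camera direction was towards higher against a negative median for heat shock (-0.0103) and photosynthesis (-0.0348).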

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

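Chosen only after the results were seen were the tests of the wild-type plants as the carriers of a shared change, the test of 264649_at as a probe set for JMJ24, the sign simulation, the simulation and splits that keep the replicate numbers, the removal of a component of the residuals, and the omission of all arrays numbered 1.

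The unnamed probe set 264649_at stands out because the mutant and 35S::JMJ24 differ from wild type in opposite directions, and the difference itself was tested: the mutant lay below 35S::JMJ24 by a log2 change of -3.86 (SE 0.106, adjusted p = 5.21e-07). It is the 1 probe set past the threshold in both lines with opposite signs. Its pattern, 7.43 ± 0.156 in the mutant, 9.41 ± 0.163 in wild type and 11.3 ± 0.098 in 35S::JMJ24 (log2, n = 3), is the one that the JMJ24 transcript itself would have if the mutation lowers it. A candidate explanation is that the probe set measures JMJ24, against a gene that follows JMJ24 dose. The pattern does not tell these apart, and the annotation used here pairs 0 probe sets with AT1G09060 and gives 264649_at no gene. Its ID lies between those of AT1G09130 and SRC2 (AT1G09070), genes beside JMJ24, which goes with a probe set for JMJ24. The IDs of AT1G09150 and AT1G09160, also beside JMJ24, lie lower. By locus number AT1G09060 falls between AT1G09010 and SRC2 instead. Whether IDs follow gene order was not tested, so the identity remains undecided.

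The 259 probe sets that separate the mutant from wild type may reflect the mutation, a structure among the arrays, or chance. Other splits of the 6 arrays gave at most 0 probe sets, but the real split is 1 of 10, too few for a share under 0.05, and the same holds for the 4 probe sets of 35S::JMJ24 against wild type and the 56 of the mutant against 35S::JMJ24, each 1 of 10 with at most 0 in the others. For the 161 probe sets of the F test, chance in how arrays fall into groups is argued against but not excluded. Of 100 splits drawn from 280, the real one included, only the real one gave as many. The highest other, 48, kept the mutant arrays together and mixed the rest. Of the 36 splits that hold 1 array of each paired number in every part, only the real one gave as many, and the highest other was again 48. After removal of the main component of the residuals 259 of the 259 were still called, with a median fold ratio of 0.985. This cannot decide whether a gradient between arrays was the whole cause. Calls favour probe sets with small residuals, so those that weigh much on that component were unlikely to be among the 259. The removal also lowers the residual spread and so favours calls (721 in all). RNA quality also remains open. Its mean shift of -0.0265 lies below the SD of the wild-type arrays (0.035) but averages controls that part, with actin at -0.0958 beyond its SD of 0.083 and ubiquitin at 0.0213. Open and untested are differences in growth or seed stock between the lines and further mutations in the mutant line.

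The changes that both lines share, those of AT1G43590, 255459_at and 261927_at and the same sign of 245 of the 259 mutant calls in 35S::JMJ24, may belong to the lines or to the 3 wild-type arrays against which both were set. The simulations do not decide whether chance in those arrays gave them, and they drew noise as independent between probe sets. A probe set was called in both in 0 of 100 simulated data sets, or 1 of 100 with the mutant and 35S::JMJ24 arrays paired by number. Unchanged groups give few calls in any comparison, so these counts were bound to be low. A simulation with effects in the mutant alone gave the same sign for at most 62.9% of calls, or 63.6% with the pairing, against 94.6% observed. It took the measured changes of the 259 as true effects. They already hold the error of the wild-type arrays, so the simulated shares are too low, by an amount not tested. Noise that moves many probe sets together was not simulated. A difference carried by the wild-type plants alone cannot give the gap of 0.66 between the lines in AT1G43590 (limma, adjusted p = 0.0138). The call of that gap is lost without mutant 2 or 35S::JMJ24 1 (adjusted p up to 0.0829), while its size stays between 0.592 and 0.73 whichever array is left out. The gap does not bear on the fall that both lines share, which wild-type plants alone could still carry. For 255459_at and 261927_at that explanation has what it needs, since the lines differ by -0.088 and -0.013, less than 2 standard errors (0.145 and 0.062 each), and a different wild-type stock or growth batch may account for it. A biological explanation, that disruption and excess of JMJ24 have an effect in common, was not tested apart from this and remains open.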

How the results depend on the processing

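Chosen after the data were seen were the settings without the arrays numbered 1, with a residual component removed, with pseudogenes above the brightest control, with a narrower pseudogene type, and with equal array medians for lists; the other settings were planned.

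The cause of the changes below was not tested, except where a setting itself uses fewer arrays or a stricter threshold. For the mutant against wild type, 259 probe sets became 68 without variance moderation, 641 with array weights, 53 without the arrays numbered 1, 721 with the residual component removed, 146 with 2 groups, 52 with a 2-fold minimum and 96 at an adjusted p under 0.01. With each array left out the count ran from 124 to 229. For 35S::JMJ24 against wild type, 4 became 2, 8, 1 and 28 in the first 4 of these settings, and 2 to 4 with an array left out. For the mutant against 35S::JMJ24, 56 became 15 without moderation, 2 without the arrays numbered 1, 176 with the component removed, 19 with 2 groups, 13 with a 2-fold minimum and 14 at an adjusted p under 0.01, and 14 to 44 with an array left out. For the F test, 161 became 31, 382, 6 and 520 in the first 4 settings, 48 at an adjusted p under 0.01, and 68 to 137 with an array left out. Array weights gave wild type 2 a weight of 3.68, and removal of the component lowers the residual spread by construction. Renewed quantile normalization gave 253, 4, 56 and 159 calls in these comparisons, and equal array medians 251, 4, 45 and 153.

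With the replicate number as a block, the counts were 607 for the mutant against wild type, with all 259 among them, 4 for 35S::JMJ24 against wild type, 76 for the mutant against 35S::JMJ24 and 292 for the F test, and among arrays of the other genotypes, 6 of the 9 arrays had their highest residual correlation with one of their own number. The share of higher calls in the mutant changed from 70 of 259 to 241 of 607. Besides AT2G11140 between the lines and 261927_at in 35S::JMJ24 (adjusted p = 0.0836), the block changed no call among the 67 values of named genes followed below, nor that of the pseudogene or the plastid list; the members of gene families were not fitted with it singly.

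The mean of the pseudogene list in the mutant lost its call after quantile normalization (0.0226), without the dimmest 30% of probe sets (0.0294), with array weights (0.0387), without the arrays numbered 1 (0.0327), with an estimated correlation or fry (0.0448) and above the brightest control (0.0491), and turned to -0.0225 without the dimmest 50%. It ran from -0.00102 to 0.0925 with an array left out. In 35S::JMJ24 it turned to -0.00207 after quantile normalization, -0.0424 without the dimmest 30%, -0.123 without the dimmest 50% (called as lower, adjusted p = 0.0172), and -0.0164 above the brightest control, was called at 0.0547 with plain probe sets only, and ran from -0.003 to 0.0905 with an array left out. These calls rest on the preset correlation; with an estimated correlation the whole list in 35S::JMJ24 had an adjusted p of 0.958, and it was not run in those settings. Between the lines it was called at 0.0718 and 0.1 without the dimmest 30% and 50% and at 0.0656 above the brightest control, turned to -0.0102 with plain probe sets only, and ran from -0.0354 to 0.0368.

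The mean of the plastid list lost its call with an estimated correlation and with fry in the mutant (-0.101), in 35S::JMJ24 (-0.143) and between the lines (0.0421). Between the lines it also lost it without the arrays numbered 1 (0.022). With an array left out it ran from -0.18 to -0.0493 in the mutant, where the call was lost without mutant 2 (-0.0618) or wild type 2 (-0.0493), and from 0.0132 to 0.0809 between the lines, where it was lost without mutant 1, mutant 3 or 35S::JMJ24 3. In 35S::JMJ24 it was kept without any single array.

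The correlation between the changes of the lines was 0.727 without the dimmest 50%, 0.611 with the component removed, and 0.524 to 0.761 with an array left out. With the component removed the covariance was 0.0138, against 0.00385 in its simulation. With the arrays of the same number paired in the simulation of unchanged groups, the mean correlation was 0.629 for pairs of the mutant and 35S::JMJ24, and 0.511 for all 3 genotypes. Probe sets called in both lines numbered 22 with the component removed and 2 to 4 with an array left out. Ubiquitin alone turned the RNA quality difference to 0.0213 in the mutant and 0.0511 in 35S::JMJ24.

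Of 67 values of named genes, 40 were called. Over all settings 0 of these 40 turned, and 147 times a call was lost, 25 of them without the arrays numbered 1, 19 without moderation and 13 with 2 groups. Renewed quantile normalization ended the calls of QQS (-0.93, adjusted p = 0.0514), AT3G60650, SDS and AT2G15630 in the mutant. Values that were not called and turned are 261927_at between the lines (-0.01), at 0.003 after quantile normalization, 0.016 with equal medians and from -0.044 to 0.015 with an array left out, AT3G21020 between the lines (0.04), from -0.015 to 0.124, and AT4G16870 in the mutant (0.10), from -0.009 to 0.182.

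Not run were all settings for the JMJ24 level, as no probe set is paired with it here, log2(value + 16), as the values are on a log scale already, and transposable element genes by type alone, as the annotation used here has no such type. Signal over background limits the pseudogenes, of which 18% lie above the brightest control, and the size of the changes of AT4G04750, AT2G40570, SDS, AT3G21020 and AT1G27285, each below it in a group.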

Other observations

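The gene families, the scalings tried on them, the loci of the residual component and the range of the plastid medians were chosen after the data were seen, while the test of neighbouring loci was written down before its result.

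Gene families were formed from symbols with a common stem and at least 15 named loci, which gave 10. They hold only loci named by such a symbol here, and membership was not checked beyond the stem. Beta-glucosidases lay lower in the mutant: 16 of 20 had a lower mean, with a median log2 change of -0.0963 (camera, adjusted p = 0.00212). The call was lost with an estimated correlation (camera, adjusted p = 0.13). The direction held after renewed quantile normalization and with equal array medians. The array medians differ little, so these scalings could hardly turn it. BGLU45 was the 1 member that passed, with a log2 change of -0.62 against wild type (adjusted p = 0.00616) and -0.64 against 35S::JMJ24 (adjusted p = 0.0148). Members that did not pass included BGLU28 (-0.59), BGLU40 (-0.52) and BGLU15 (-0.33). Of 26 loci with the stem CYP, used for cytochrome P450 genes, 15 had a lower and 11 a higher mean in the mutant. Their median was -0.0952 (camera towards lower, adjusted p = 0.0427), a call lost with an estimated correlation (camera, adjusted p = 0.13). CYP71B24 (-1.16, limma, adjusted p = 0.00553) and CYP71B6 (-0.34, adjusted p = 0.0271) fell. The camera call of the CYP loci in the mutant was also lost without mutant 1 (adjusted p = 0.123), mutant 2 (0.053), 35S::JMJ24 2 (0.0581), wild type 2 (0.102) or wild type 3 (0.0609).

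In 35S::JMJ24, glycosyltransferases of the UGT family lay higher, 41 of 47 with a median of 0.111 (camera, adjusted p = 0.000603). The call was lost with an estimated correlation (camera, adjusted p = 0.185). The direction held under both scalings, which could hardly turn it. By limma 0 of the 47 passed singly. Examples are UGT73B5 (0.36), UGT73D1 (0.31) and UGT76B1 (0.29). In the mutant the family was not called (median 0.0408, adjusted p = 0.149), and the difference between the lines was not called either (median -0.0681, adjusted p = 0.31). Of the CYP loci 16 had a lower and 10 a higher mean in 35S::JMJ24 (median -0.074, camera towards lower, adjusted p = 0.0369). That call was lost with an estimated correlation (camera, adjusted p = 0.185). It was also lost without mutant 2 (adjusted p = 0.0524), 35S::JMJ24 1 (0.083), 35S::JMJ24 3 (0.181) or wild type 2 (0.0814). The other 7 families were not called in any comparison.

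Genes were also picked for their variation between arrays of a genotype. The 20 named loci with the highest weight on the component of the residuals that holds 40.1% of the variation within genotypes all had the same sign, and 18 were lowest on wild type 1 of all 9 arrays. WRKY53 read 7.90, 9.52 and 9.83 on the wild-type arrays. AT1G19380 read 9.19, 10.7 and 11.3, and AT4G11000 spanned 2.44 on them.

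Plastid-encoded genes moved together between arrays of wild type: their medians spanned 0.255 on the log2 scale, more than the difference of either line from wild type (-0.099 for the mutant and -0.132 for 35S::JMJ24).

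A hypothesis was that loci changed in the mutant lie beside each other on the chromosomes. Among the 146 called loci there were 12 pairs lying 5 or fewer measured loci apart, where 10000 random draws gave a median of 8 pairs and a 95th percentile of 13 (one-sided permutation test, p = 0.113). The draws do not exclude chance. The longest run held AT2G46910 (-1.5), AT2G46915 (-0.80), AT2G47010 (-0.73) and AT2G47020 (-0.42), all lower in the mutant, and was singled out after its values were seen.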
